A study of Mus musculus with 6 samples.

How the data were processed

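RNA was measured by RNA-seq in splenic B cells that had been isolated by magnetic cell separation from 12-week-old mice and cultured with BAFF for 6 h, as the labels describe. BAFF is a cytokine of the tumour necrosis factor family that supports B cell survival. There were 6 libraries in 2 groups. The 3 control libraries came from mice with the CD19-Cre transgene, which drives Cre recombinase in B cells. The 3 flox libraries came from littermates with CD19-Cre and floxed nfkb2 alleles. Per the labels' protocols, RNA was extracted with Trizol, enriched for polyadenylated RNA, prepared with the TruSeq RNA kit and sequenced on a HiSeq2000 with reads of 100 bp and a target of 30 M reads per sample. The strandedness of the libraries is not stated in these protocols. The labels do not say that each library came from its own mouse, so the p-values measure the spread between these samples, which may be technical.

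The authors deposited whole-number read counts per gene symbol for the 6 libraries, with no normalization, and the counts were used as deposited. Per the submitters' processing notes, CASAVA 1.8.2, TopHat2 2.0.4 and Cufflinks 2.0.2 were used with the mm9 build of the mouse genome. The program that counted the reads, its annotation and its treatment of strand and of reads with several matches are not given in the sources used here. The table held 23284 named genes. Of these, 25 carried names that a spreadsheet had turned into dates, which together held 0.195% of the counts. They stayed in the library totals and the tests, and their genes are not named here. Of the names, 20683 (88.8%) were symbols in the RefSeq annotation of GRCm38 and 2359 more were synonyms there. That annotation belongs to another build than the counts. It served only for names and for which genes lie next to or overlap each other, and no coordinates are given.

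Library totals lay between 13.7 and 20.5 M counts (M, 10 to the power of 6). A gene with no counts in a library is below 3 counts, which corresponds to between 0.146 and 0.219 CPM (counts per M counts of the library). Such floors cover counting error only. Reads that fit near-identical copies of a gene cannot be assigned to a copy with certainty. Gapdh, named after its values were seen, held only between 61 and 120 counts per library. The values of Hspa1a and Hspa1b, of the Bcl2a1 genes and of the ribosomal protein genes are uncertain for this reason, as are those of overlapping genes such as Nfkb2 and Psd. The counts of every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom between 3.71 and 22.6, so no library was taken for a copy of another.

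Genes were tested with edgeR 4.0.16 in R 4.3.3. The counts were filtered with filterByExpr at a minimum count of 10 and scaled with TMM factors, which lay between 0.992 and 1.01. The quasi-likelihood F-test compared the flox with the control libraries, and p-values were adjusted by Benjamini-Hochberg over the 11930 genes tested. These genes held 99.9% of the counts. A gene was called when its adjusted p was under 0.05. Log2 fold changes are flox minus control, and their standard errors (SE) were derived from the F statistics. CPM values are given as mean ± SD. The tests planned for a normalized unit were run as alternatives on log2 CPM.

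The following 33 gene lists were written from general knowledge before the data were examined: NF-kB subunits, NF-kB inhibitors and feedback, non-canonical pathway signalling, NF-kB responsive genes, anti-apoptotic genes, pro-apoptotic genes, BAFF and TNF receptor family, T cell interaction molecules, MHC class II presentation, migration and adhesion, BCR signalling, B cell identity, follicular, marginal zone, transitional and immature, B-1 and germinal centre B cells, plasma cells, cell cycle, MYC-linked growth and ribosome biogenesis, glycolysis, interferon response, immediate early and handling stress, unfolded protein response, markers of T cells, NK cells, monocytes and macrophages, neutrophils and granulocyte precursors, dendritic cells, erythroid cells, platelets and megakaryocytes, and stromal and endothelial cells, and a list of sex-linked genes. The last was used for no test. Of 464 entries, 5 had no row, among them the immunoglobulin constant genes Ighm, Ighd, Ighg1 and Igha, and 1 was matched by a synonym. The other 32 lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, each adjusted over the 32 lists. The design, the lists, the rule for named genes and a set of alternatives were fixed before the data were examined.

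Named genes followed that rule. It takes the 5 NF-kB subunits. It takes the 10 largest rises and the 10 largest falls among called genes with no overlap between the groups, leaving out predicted and unnamed genes. From each list it takes up to 4 tested members with the lowest p. It also takes Icosl, Cd40, Tnfrsf13c, Bcl2, Bcl2a1a, Bcl2l1, Mcl1, Cxcr5, Ccr7, Cr2, Fcer2a and Cd1d1. Any other gene named is said to have been chosen after its values were seen.

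The procedure was tested on simulated counts for 11835 genes drawn from the means and depths of these libraries. For this comparison edgeR recovered 43.3% of genes changed by 0.4 on the log2 scale, 73.8% of those changed by 0.8 and 95.4% of those changed by 1.5. Of its calls, 4.79% fell on unchanged genes. With DESeq2 this share was 11.3%.

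The alternatives set beforehand were other pseudocounts, filters, variance models and scalings, limma-voom, DESeq2 1.42.0, a minimum fold of 1.2, a term for the replicate number, and the omission of each library in turn. After the data had been seen, further alternatives were added. They left out the library richest in markers of other cell types in each group, thinned the counts to equal depth, took Nfkb2 or the Hspa1 genes out of their lists, and ran limma-trend with a pseudocount of 1. The values and figures were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.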

Results

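Gene expression was compared between BAFF-stimulated splenic B cells of nfkb2 fl/fl CD19-Cre mice (flox) and of CD19-Cre littermates (control), with 3 libraries in each group. All cells had been stimulated for 6 h. The comparison addresses which transcripts differ between the genotypes in B cells exposed to BAFF. There was no unstimulated group, so differences that were present before BAFF cannot be told apart. The control libraries held 15.3, 19.0 and 13.7 M counts and the flox libraries 20.5, 17.5 and 19.7 M. The series title and the sample labels name nfkb2 as the floxed gene, whereas the design text of the series names rel. The levels of both genes are given below for every library.

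Nfkb2, which encodes the precursor of the NF-kB subunit at the end of the non-canonical pathway, fell to 39.5% of its control level. Its level was 680, 678 and 700.0 CPM in the control libraries and 273, 260.4 and 279 CPM in the flox libraries. The log2 fold change was −1.34 (SE 0.0531, edgeR adjusted p = 4.466e-06). An exact two-sided permutation test of this gene alone gave p = 0.1, the smallest value that 3 against 3 libraries allow. The table holds a value per gene and not per exon, so it does not separate reads inside and outside the floxed part. Rel, named in the design text, was at 185 ± 19.3 CPM in control and 151 ± 32.1 CPM in flox libraries (SD, n = 3). Its log2 fold change of −0.29 (SE 0.138) did not pass the test (edgeR adjusted p = 0.354), and the 2 groups overlapped.

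The other NF-kB subunit genes did not pass the test either. The log2 fold change was 0.12 (SE 0.0567) for Nfkb1, −0.10 (SE 0.0676) for Relb and −0.04 (SE 0.0524) for Rela. The list of 5 subunits was lower by camera (adjusted p = 6.13e-11). With an estimated correlation its adjusted p = 0.168, and without Nfkb2 its camera adjusted p = 0.464. The adjusted p of the list was 0.0969 after quantile normalization and 0.061 with limma-trend at a pseudocount of 0.1.

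**Figure D1:**
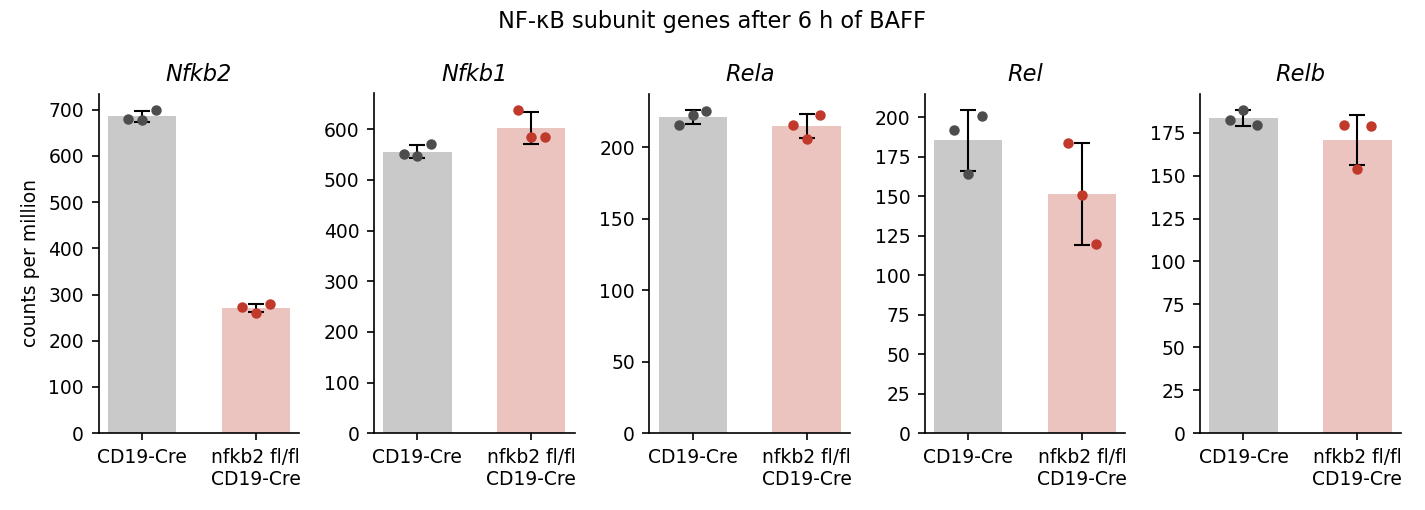
Level of the 5 NF-kB subunit genes in CPM (vertical axis, from 0) in the 3 CD19-Cre and 3 nfkb2 fl/fl CD19-Cre libraries. Points are libraries, bars are means and error bars are SD. Nfkb2 is at 686 ± 12.3 CPM in control and 271 ± 9.54 CPM in flox libraries, and the other 4 genes did not pass the test.

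Across the transcriptome, 258 of 11930 genes tested were called, 162 higher and 96 lower in flox libraries. The rises were larger and lay in genes of lower expression. Of the called genes, 42 rose and 2 fell by more than 2-fold. The median log2 fold change was 0.63 among the genes that rose and −0.41 among those that fell, and their median control levels were 26.4 and 184 CPM. In each of the 258 genes the 3 libraries of a group all lay on the same side of the other 3. This held for 20.9% of all genes tested, where chance gives 10%. The median log2 fold change of all genes was −0.0022. The number of calls depended on single libraries. It was 34, 49 and 64 without control replicate 1, 2 and 3, and 305, 105 and 911 without flox replicate 1, 2 and 3. Rises outnumbered falls in these fits except without flox replicate 3, where 438 genes were higher and 473 lower. Flox replicate 3 held 13510 CPM of the ribosomal RNA gene Rn45s, named after its values were seen, against 3035 to 6465 CPM in the other 5 libraries, and had the lowest sample weight in limma, 0.412. All 258 genes kept their direction in these 6 fits, which was fixed beforehand because their groups did not overlap. Of the 258 genes, 32 were called in each of the 6 fits. DESeq2 called 551 genes, among them all 258, and a fit without the library richest in markers of other cell types in each group called 143, of which 112 were among the 258.

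The 10 largest rises lay between 1.72 and 2.93 on the log2 scale. The metallothionein genes Mt1 and Mt2, which encode metal-binding proteins, rose by 2.93 (SE 0.571) and 2.90 (SE 0.514). Without flox replicate 1 their log2 fold changes were 2.20 and 2.11, and each gene was called in 2 of the 6 fits without a library. Hspa1a and Hspa1b, near-identical genes of inducible heat shock proteins whose separate values are uncertain, rose by 2.53 (SE 0.328) and 2.51 (SE 0.315). Hmox1, the gene of the haem-degrading enzyme haem oxygenase, rose by 1.88 (SE 0.331). Il10, which encodes an anti-inflammatory cytokine, rose by 1.99 (SE 0.299) from 0.980 ± 0.126 to 3.90 ± 1.11 CPM (SD, n = 3). Mgll, the gene of a lipase of monoacylglycerols, rose by 1.72 (SE 0.187). The list of large rises also held Efr3b (2.64), the collagen gene Col5a3 (2.30) and the phosphodiesterase gene Pde4c (1.84). Efr3b was at 0.447 ± 0.146 CPM in control and 2.87 ± 1.39 CPM in flox libraries (SD, n = 3). Its log2 fold change ranged from 0.52 to 2.95 over 22 alternative settings, and its call was lost in 9 of them. The adjusted p of these 10 genes ranged from 0.00386 for Mgll to 0.0347 for Mt1. Markers of T cells, myeloid cells and red cells were also at their highest in flox replicate 1, as described below for each library.

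Apart from Nfkb2, the largest fall was that of Psd, by 1.44 on the log2 scale (SE 0.0576, adjusted p = 4.466e-06). In the RefSeq annotation of GRCm38 Psd overlaps the end of Nfkb2 on the opposite strand by 316 bp. Use of strand in the counting is not stated, so reads of this stretch cannot be assigned to 1 of the 2 genes. The remaining large falls were smaller. Lpcat1, which encodes an acyltransferase of lysophosphatidylcholine, fell by 0.75 (SE 0.0513) and the sulfotransferase gene Chst10 by 0.72 (SE 0.0556). Faah, the gene of fatty acid amide hydrolase, fell by 0.73 (SE 0.126) and the serine protease gene Prss12 by 0.73 (SE 0.120). Ccdc99, the glutamate receptor gene Grm6, the chemokine receptor gene Ccr7 and Ticam2, an adaptor gene of Toll-like receptor signalling, had log2 fold changes of −0.71, −0.70, −0.68 and −0.68. The adjusted p of these 8 genes was at most 0.0248. Of 49 called genes named by the rule, 13 were called in each of the 6 fits without a library. They were Nfkb2, Psd, Mgll, Lpcat1, Chst10, Hspa1b, Bmf, Sell, Gpr183, P2ry10, Asb2, Myb and Cd93.

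**Figure D2:**
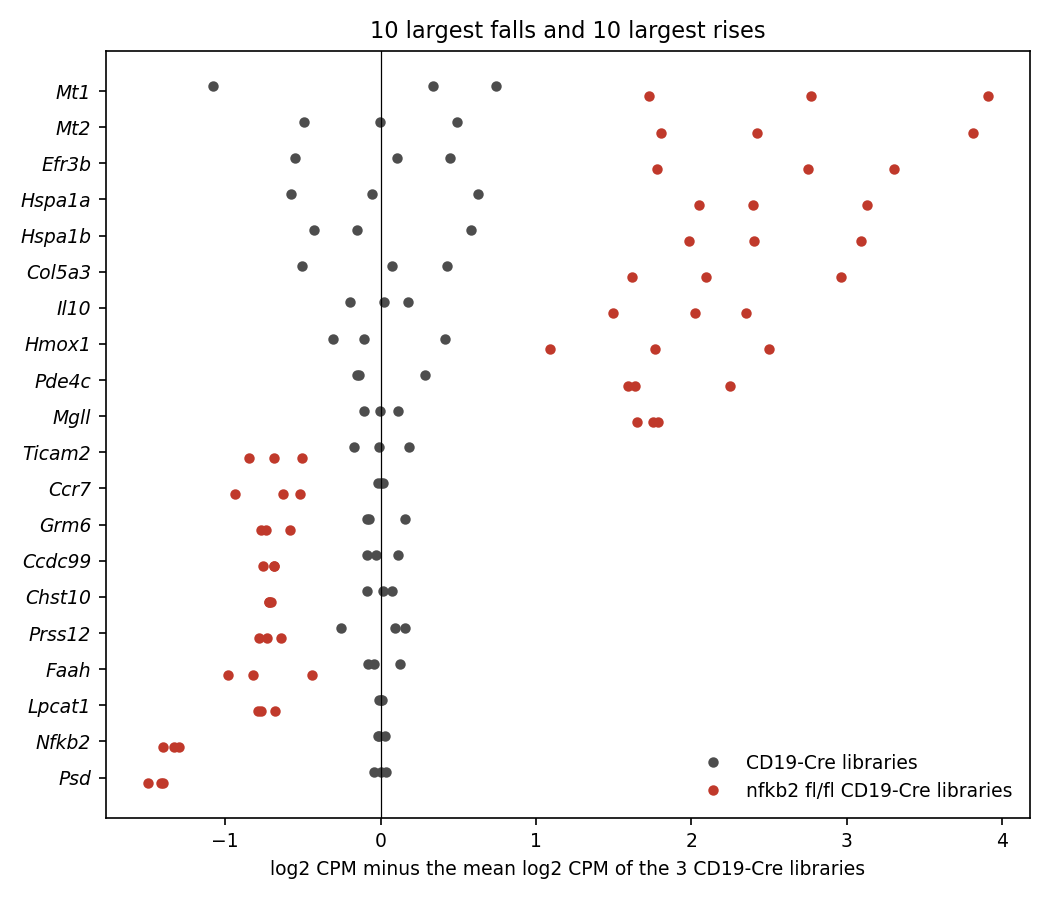
Log2 CPM of each library minus the mean log2 CPM of the 3 CD19-Cre libraries (horizontal axis) for the 10 genes with the largest falls and the 10 with the largest rises (vertical axis). Points are libraries, and in each of the 20 genes the 2 groups do not overlap, from Psd (−1.44) to Mt1 (2.93).

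Genes that promote cell death rose in part. Of 15 pro-apoptotic genes tested, 2 were called, and both encode BH3-only proteins, which trigger the mitochondrial pathway of apoptosis. Bmf rose by 0.73 (SE 0.0717, adjusted p = 0.003807) from 101 ± 8.94 to 168 ± 8.75 CPM (SD, n = 3), and Bbc3 rose by 0.68 (SE 0.113, adjusted p = 0.0191). The same 2 genes passed when adjusted over the list alone. Pmaip1 (0.24) and Apaf1 (0.15) did not pass. The list was higher by camera (adjusted p = 0.00303), with an adjusted p = 0.206 with an estimated correlation. Among 14 anti-apoptotic genes, 1 rose, Gadd45b by 0.35 (SE 0.0658, adjusted p = 0.0297). Adjusted over the list alone, 1 was higher and 3 were lower. Bcl2, the founding survival gene of its family, had a log2 fold change of −0.41 (SE 0.0935, adjusted p = 0.0646) and did not pass over all genes. Bcl2a1d (−0.32), Birc3 (−0.18), Mcl1 (−0.04), Bcl2l1 (0.33) and Bcl2a1a (0.22) did not pass either. The list did not pass by camera (adjusted p = 0.32).

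Genes typical of B cell subsets moved in different directions. Of 14 marginal zone B cell genes tested, 7 rose over all genes and 10 adjusted over the list alone, and none fell. Asb2 rose by 1.28 (SE 0.152), Myof by 0.99 (SE 0.128), Cd36, a scavenger receptor gene, by 0.69 (SE 0.0953) and Fcrl5, an Fc receptor-like gene, by 0.64 (SE 0.0791). Their adjusted p lay between 0.005901 and 0.008269. Cd9, Tm6sf1 and Plac8, named after their values were seen, also rose. Cr2 and Cd1d1, whose products are abundant on marginal zone B cells, had log2 fold changes of −0.07 (SE 0.0716) and −0.11 (SE 0.0645) and did not pass. Of 8 transitional and immature B cell genes, 3 rose, the transcription factor gene Myb by 0.91 (SE 0.113), Cd93 by 0.78 (SE 0.102) and the recombinase gene Rag1 by 1.39 (SE 0.205). With p-values adjusted over the list alone 4 passed, among them Rag2 (2.12, SE 0.458, adjusted p = 0.051 over all genes), which was at 0.341 CPM in control libraries. Of 7 B-1 cell genes, 2 rose, Bhlhe41 by 1.15 (SE 0.162) and Zbtb32 by 0.78 (SE 0.139), both transcription factor genes, and 3 passed adjusted over the list alone. Plscr1 (0.54) and Itgam (1.22) did not pass over all genes. Itgam, also a myeloid gene, was at 14.9 CPM in flox replicate 1 and between 2.70 and 4.70 CPM in the other 5 libraries, and its log2 fold change was 0.38 without flox replicate 1.

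In contrast, 4 of 7 follicular B cell genes fell, and adjusted over the list alone the same 4 were lower and 1 was higher. The latter, Klf2, a transcription factor gene named after its values were seen, had a log2 fold change of 0.43 (SE 0.101, adjusted p = 0.0694 over all genes). Sell, which encodes the homing receptor L-selectin, fell by 0.56 (SE 0.0578, adjusted p = 0.00386) from 1213 ± 5.12 to 825 ± 46.7 CPM (SD, n = 3). Ccr7 had a log2 fold change of −0.68 (SE 0.0945), Fcer2a, the gene of the low-affinity IgE receptor, −0.41 (SE 0.0855, adjusted p = 0.0462) and Cxcr5, the gene of the follicle-homing receptor, −0.24 (SE 0.0519, adjusted p = 0.0475). Fcer2a and Cxcr5 were each called in only 1 of the 6 fits without a library. Their calls were lost in 12 and 15 of 23 alternative settings. By camera, the marginal zone (adjusted p = 3.57e-11), immature (4.77e-09) and B-1 (1.49e-05) lists were higher and the follicular list was lower (4.52e-05). With an estimated correlation none passed (adjusted p = 0.12, 0.191, 0.411 and 0.191 in the same order). The estimated correlations between genes were 0.0402, 0.383, 0.917 and 0.196 in that order. For comparison, the T cell markers had 0.775 and the monocyte and macrophage markers 0.631. By fry the marginal zone list passed (adjusted p = 0.0218), and the immature (0.059), B-1 (0.201) and follicular (0.059) lists did not. After quantile normalization the follicular list had an adjusted p of 0.0858. Summed markers of T cells, myeloid cells and red cells were higher in flox than in control replicates 1 and 2. Without the richest library of each group, 10 of the 16 called subset genes were still called. Their direction could not turn, because the groups did not overlap in any called gene.

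**Figure D3:**
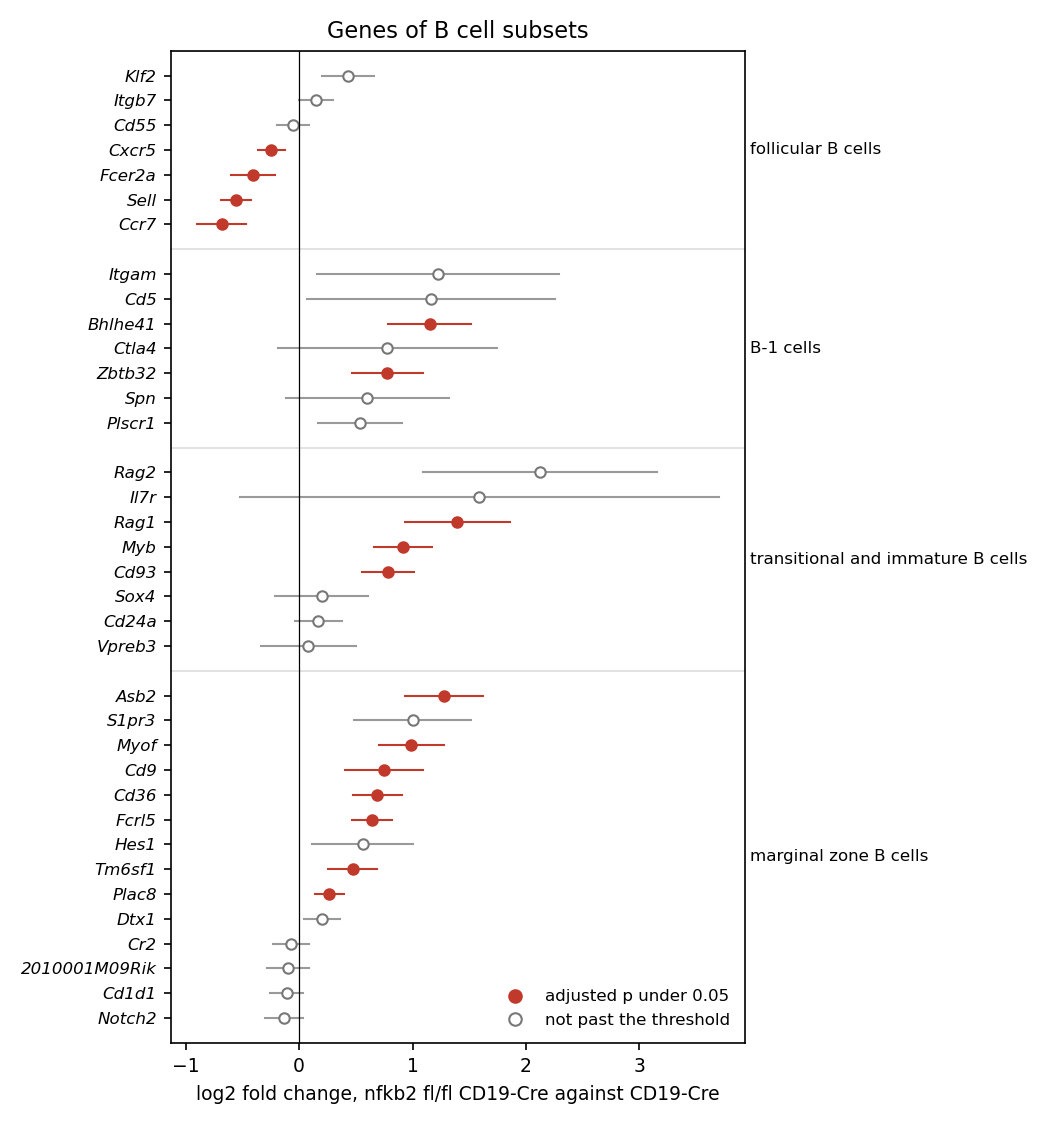
Log2 fold change, flox against control (horizontal axis), of the tested members of the 4 B cell subset lists (vertical axis). Points are estimates from 3 against 3 libraries and lines are 95% confidence intervals; filled points passed the test. Of the genes shown, 7 marginal zone, 3 immature and 2 B-1 genes rose and 4 follicular genes fell.

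Some receptors that guide B cell movement fell and others did not pass. Of 23 migration and adhesion genes, 6 fell and none rose over all genes, and adjusted over the list alone 6 were lower and 3 higher. Besides Ccr7, Sell and Cxcr5, the falls were in Gpr183, the gene of an oxysterol receptor, by 0.57 (SE 0.0619, adjusted p = 0.00386), P2ry10 by 0.50 (SE 0.065, adjusted p = 0.006931) and Gpr174 by 0.43 (SE 0.0529, adjusted p = 0.006146), both genes of lysophosphatidylserine receptors. S1pr1 (0.17), Cxcr4 (0.06) and Ccr6 (−0.09), named after their values were seen, did not pass. The median of the list was −0.06 over all libraries and 0.02 without flox replicate 3. By camera it was lower (adjusted p = 0.00131), as by fry (adjusted p = 0.0218). Its adjusted p was 0.181 with an estimated correlation, 0.275 after quantile normalization and 0.186 with limma-trend at a pseudocount of 0.1.

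Of 13 genes of MHC class II presentation, 2 fell over all genes and 4 adjusted over the list alone. H2-DMb2, a gene of the peptide-loading complex, fell by 0.39 (SE 0.0479, adjusted p = 0.006146) and Ctss, the gene of the protease cathepsin S, by 0.34 (SE 0.0654, adjusted p = 0.0323). Ctss was called in only 1 of the 6 fits without a library, and its call was lost in 9 of 23 alternative settings. H2-Aa was at 4651 ± 243 CPM in control and 3640 ± 405 CPM in flox libraries (SD, n = 3), with a log2 fold change of −0.35 and an adjusted p of 0.0696 by edgeR. H2-Oa (−0.32) did not pass over all genes either. The list was lower by camera (adjusted p = 0.000133), with an adjusted p = 0.411 with an estimated correlation and 0.0691 after quantile normalization. Of 17 T cell interaction molecules, 1 fell over all genes. This was Icosl, the gene of the ICOS ligand, which fell by 0.35 (SE 0.0596, adjusted p = 0.0201) from 529 ± 7.86 to 414 ± 26.4 CPM (SD, n = 3). Its call was lost in 7 of 23 alternative settings. Adjusted over the list alone, 2 were lower and 2 higher. Tnfsf4 (0.456 CPM in control and 1.32 CPM in flox libraries), Cd83 (−0.25), Icam1 (0.23) and Cd40 (−0.14) did not pass over all genes. The median of this list was −0.13 and its mean 0.06, and it did not pass by camera (adjusted p = 0.173).

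**Figure D4:**
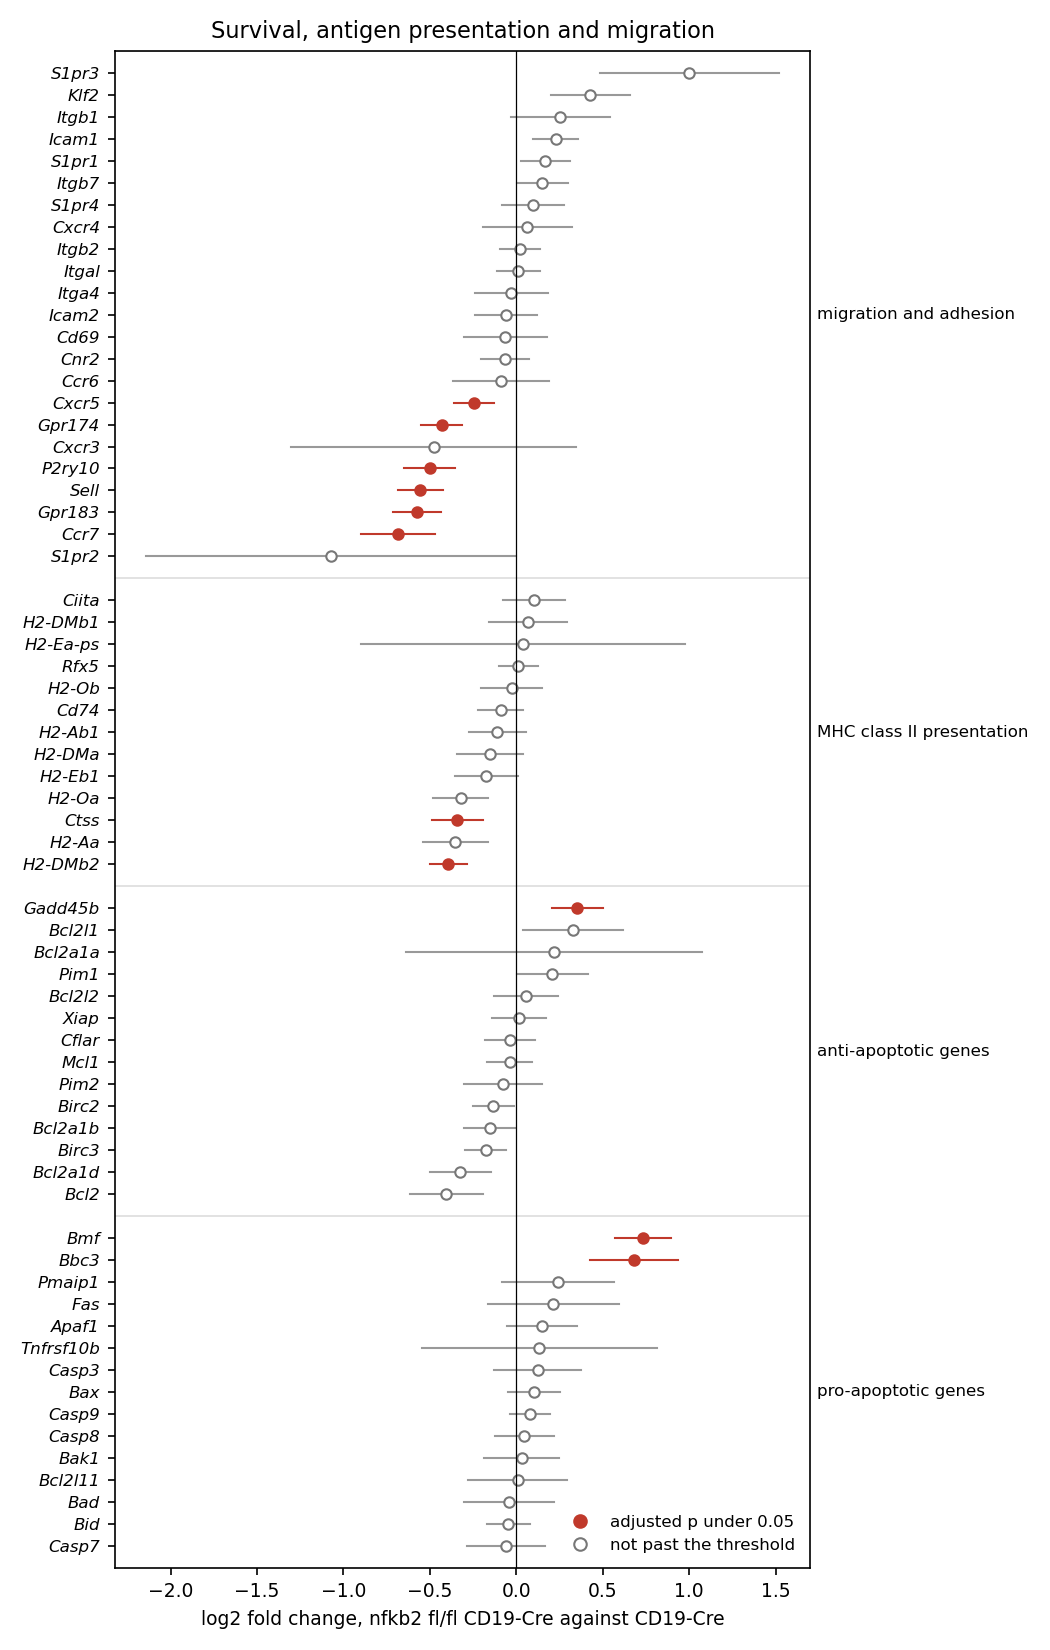
Log2 fold change, flox against control (horizontal axis), of the tested pro-apoptotic, anti-apoptotic, MHC class II and migration genes (vertical axis). Points are estimates from 3 against 3 libraries and lines are 95% confidence intervals; filled points passed the test. Bmf (0.73), Bbc3 (0.68) and Gadd45b (0.35) rose, and H2-DMb2, Ctss and 6 migration genes fell.

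The NF-kB responsive genes did not move as a group. Of 30 tested, 2 rose, the chemokine gene Ccl22 by 1.41 (SE 0.300, adjusted p = 0.0481) and Gadd45b by 0.35. The call of Ccl22 was lost in 11 of 23 alternative settings and that of Gadd45b in 7. Adjusted over the list alone, 5 were higher and 4 lower. Cd83 and Bcl2a1d did not pass over all genes, and the list had an adjusted p of 0.932 by camera. Of 10 NF-kB inhibitors and feedback genes, 1 rose, Nfkbid by 0.40 (SE 0.0733, adjusted p = 0.026), which encodes a nuclear IkB protein. For these genes, 1 was higher and 1 lower adjusted over the list alone. The call of Nfkbid was lost in 7 of 23 alternative settings. Bcl3 (−0.21), Nfkbia (−0.19) and Nfkbib (−0.09) did not pass, nor did the list (adjusted p = 0.908). None of the 9 non-canonical pathway genes passed, either over all genes or adjusted over the list alone. Birc3 (−0.18), Birc2 (−0.13) and Traf3 (0.09) were among them, and the list had an adjusted p of 0.304. None of the 12 genes of the BAFF and TNF receptor family passed in either way. Tnfrsf13c, the BAFF receptor gene, had a log2 fold change of 0.16 (SE 0.135), and Tnfrsf13b one of 0.21. The list did not pass (adjusted p = 0.212).

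The general B cell programme showed few changes. Of 16 B cell identity genes, 1 fell, Pou2af1, the gene of a B cell transcriptional coactivator, by 0.46 (SE 0.0584, adjusted p = 0.006892). It was also the sole call adjusted over the list alone. Cd72 (0.32), Blk (0.16) and Fcrla (0.21) did not pass, nor did the list (adjusted p = 0.913). None of 24 BCR signalling genes passed over all genes, and 3 were higher and 2 lower adjusted over the list alone. Card11 (0.27), Ptpn6 (0.33), Pik3cd (−0.24) and Syk (−0.21) had the lowest p. The list had an adjusted p of 0.377.

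Of 26 cell cycle genes, 1 fell over all genes, Mcm5, the gene of a subunit of the replicative helicase, by 0.46 (SE 0.0684, adjusted p = 0.0119). There were 5 lower and 4 higher genes adjusted over the list alone. Mcm4 (−0.23), the inhibitor gene Cdkn1a (0.95) and Ccnd2 (0.55) did not pass over all genes. The list was lower by camera (adjusted p = 0.0315), with an adjusted p = 0.586 with an estimated correlation. This call was lost without control replicate 1 (adjusted p = 0.458), flox replicate 2 (0.0625) or flox replicate 3 (0.178), and with limma-trend at a pseudocount of 0.1 (0.0626). None of 16 genes of MYC-linked growth and ribosome biogenesis passed in either way. That list had an adjusted p of 0.178 by camera and passed as higher without flox replicate 2 (0.0285). Of 14 glycolysis genes, the glucose transporter gene Slc2a3 fell by 0.33 (SE 0.0535, adjusted p = 0.0178), also the sole call adjusted over the list alone. Its call was lost in 8 of 23 alternative settings. The list had an adjusted p of 0.377. None of 14 unfolded protein response genes passed in either way. By camera their adjusted p was 0.178, and without flox replicate 2 the list passed as higher (0.039).

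Of 17 immediate early and stress genes tested, 5 rose over all genes, 10 passed adjusted over the list alone and 12 did not pass over all genes, although every estimate was above 0. Dnajb1 (0.02) and Hspa8 (0.24), named after their values were seen, were among the 12. Besides Hspa1a and Hspa1b, the transcription factor genes Egr1 rose by 0.65 (SE 0.0866, adjusted p = 0.007394) and Atf3 by 1.57 (SE 0.307, adjusted p = 0.0353), as did Egr3, named after its values were seen. The call of Atf3 was lost in 10 of 23 alternative settings and that of Egr1 in 3. The list was higher by camera (adjusted p = 2.19e-12) and stayed so without Hspa1a and Hspa1b (adjusted p = 1.21e-07). With an estimated correlation its adjusted p = 0.191. None of 18 interferon response genes passed in either way, with Mx1 at 3.45 ± 0.515 CPM in control and 6.93 ± 3.63 CPM in flox libraries (SD, n = 3). The list had an adjusted p of 0.155, with a median of 0.27. Without flox replicate 1 the median was −0.18 and the list passed as lower (adjusted p = 0.0354). It passed as higher without control replicate 3 (0.0175), flox replicate 2 (0.0041) or flox replicate 3 (0.0138).

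None of 6 plasma cell genes passed over all genes and 4 were higher adjusted over the list alone. Prdm1, a master regulator of plasma cell formation, had a log2 fold change of 0.68 (SE 0.172, adjusted p = 0.0861). The list was higher by camera (adjusted p = 0.000936), with an adjusted p = 0.411 with an estimated correlation. Its summed level was highest in the libraries richest in markers of other cells, flox replicate 1 (1798 CPM) and control replicate 3 (1278 CPM), and between 906 and 1220 CPM in the other 4. Without these 2 libraries its camera adjusted p was 5.48e-06. None of 8 germinal centre genes passed over all genes and 2 were lower adjusted over the list alone. Gcet2 had a log2 fold change of −2.71 (SE 0.778), with 5.09 ± 5.99 CPM in control and 0.765 ± 0.199 CPM in flox libraries (SD, n = 3). Control replicate 1 held 12.0 CPM of Gcet2 against 1.43 and 1.84 CPM in control replicates 2 and 3, and without it the log2 fold change was −1.07. The list did not pass by camera (adjusted p = 0.0685). It passed as lower without control replicate 2 (adjusted p = 0.000311), control replicate 3 (0.013) or flox replicate 1 (0.0354), and without the richest library of each group (0.00637).

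Markers of cells other than B cells differed between libraries. Summed over T cell, monocyte and macrophage, neutrophil and erythroid markers, they reached 780 CPM in flox replicate 1. They reached 290 and 328 CPM in flox replicates 2 and 3, and 234, 238 and 371 CPM in control replicates 1, 2 and 3. T cell markers alone were at 381 CPM in flox replicate 1 and between 155 and 211 CPM in the other 5 libraries. Much of these sums came from Cd2 (107 to 148 CPM) and Lck (37.1 to 63.6 CPM), which differed less between libraries. Cd8a was at 9.17 CPM in flox replicate 1, 1.76 CPM in control replicate 3 and at most 0.764 CPM in the other 4 libraries. By camera the lists of T cell (adjusted p = 0.0206), monocyte and macrophage (0.00326), dendritic cell (0.00976) and erythroid markers (0.0388) were higher. With an estimated correlation none passed (adjusted p = 0.586, 0.505, 0.453 and 0.586). Single genes passed in 2 of these lists, Hmox1 among 8 macrophage markers and Ermap, an erythroid membrane protein gene, among 5 erythroid markers, where it rose by 1.08 (SE 0.191, adjusted p = 0.0242). Adjusted over the list alone, 1 of 10 T cell markers, 1 macrophage, 4 of 8 dendritic and 1 erythroid marker passed, all higher. Without flox replicate 1 the median of the T cell list moved from 1.31 to −0.54 (adjusted p = 0.779), and the dendritic (0.166) and erythroid (0.806) lists no longer passed. The T cell and erythroid lists also no longer passed without control replicate 1 (both 0.0772) or 2 (both 0.0763), with limma-trend at a pseudocount of 0.1 (both 0.0992) or after quantile normalization (0.0691 and 0.0832). Without the richest library of each group the T cell (0.0836) and dendritic (0.0535) lists did not pass, and the erythroid list did (0.000807). The lists of NK cell (adjusted p = 0.178), neutrophil (0.178), platelet (0.0592) and stromal markers (0.304) did not pass, and none of their tested members did. Without control replicate 3 the NK cell (0.0354) and neutrophil (0.0097) lists passed as higher, without flox replicate 2 the neutrophil (0.0041) and platelet (0.0274) lists, and without control replicate 2 the platelet list (0.0139). Without flox replicate 1 the stromal list passed as lower (0.0346).

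**Figure D5:**
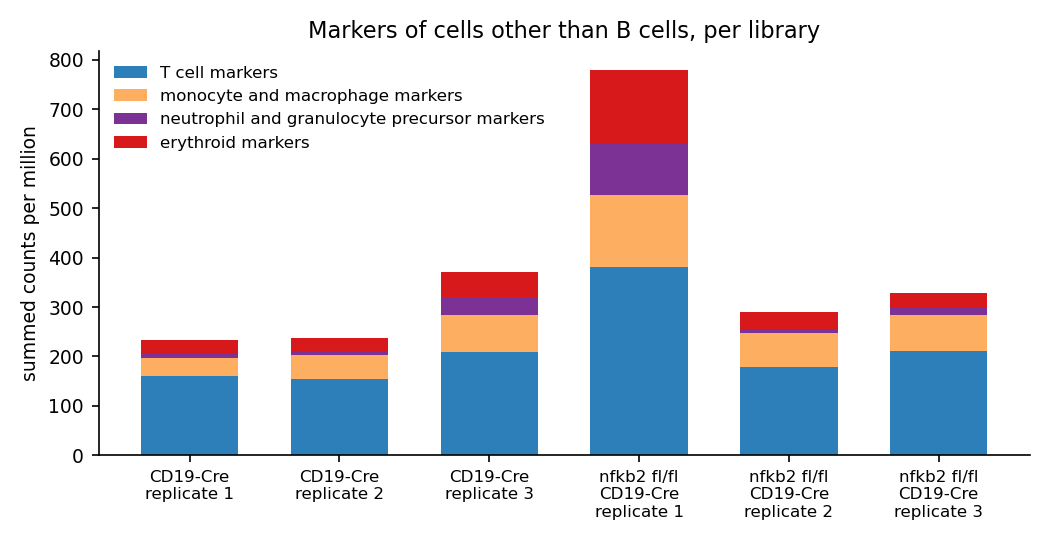
Summed CPM (vertical axis, from 0) of markers of T cells, monocytes and macrophages, neutrophils and erythroid cells in each of the 6 libraries (horizontal axis). Each bar is a library, and flox replicate 1 is the highest at 780 CPM.

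The libraries resembled each other closely in overall expression. Over the genes tested, Pearson's r of log2 CPM lay between 0.984 and 0.993 within groups (median 0.990, 6 pairs) and between 0.978 and 0.992 between groups (median 0.988, 9 pairs). These correlations are across genes, which are not independent replicates. The first principal component held 44.8% of the variance and did not part the groups, with flox replicate 1 at 36.6 and control replicate 3 at 5.06. The next component held 22.9% and placed flox replicates 2 and 3 at −19.0 and −16.5, apart from the controls at 9.73, 2.09 and 19.7. Flox replicate 1, at 3.96, lay among the controls on it.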

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

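Nfkb2 was lower and called under every setting tried, with log2 fold changes between −1.36 and −1.31. The number of genes called, 258 with edgeR, depended on the method and the libraries. It was 87 with limma without the variance trend, 820 with sample weights (438 higher and 382 lower), 551 with DESeq2 and 40 when a fold of at least 1.2 was tested. It ranged from 34 without control replicate 1 to 911 without flox replicate 3, and was 143 without the library of each group richest in markers of other cell types, a fit added after the data had been seen. With the replicate number as a replicate block it was 124 (79 higher and 45 lower), of which 121 were among the 258, where the erythroid list no longer passed (adjusted p = 0.0966) and the germinal centre list passed as lower (0.0164). The same-numbered libraries had correlations of −0.251, 0.217 and −0.324 in their deviations from the group means. Pairs with different numbers lay between −0.382 and 0.521, so these values cannot decide whether the numbers paired the samples. Of the 32 lists, 15 passed by camera, 11 with limma-trend at a pseudocount of 0.1 (9 higher and 2 lower), 9 after quantile normalization, 3 by fry and 0 with an estimated correlation, and between 12 and 19 without a library. The 3 by fry were the NF-kB subunit, migration and marginal zone lists (adjusted p = 0.0218 each). The other lists that passed by camera did not pass by fry, such as the pro-apoptotic and stress (both 0.059), MHC class II (0.17), plasma cell (0.201) and cell cycle (0.381) lists. The median of the interferon list ranged from −0.1778 without flox replicate 1 to 0.4699 without flox replicate 3. That of the T cell markers ranged from −0.5367 without flox replicate 1 to 2.3423 without control replicate 3. The cause of these differences was not tested.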

Other observations

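The gene groups in the next 2 paragraphs and all tests below except the regrouping of libraries were chosen after the result was seen. Of 79 ribosomal protein genes tested, 70 had estimates below 0 and 7 were called, all lower, such as Rps15a by 0.45 (SE 0.0779), Rps17 by 0.41 (SE 0.0813) and Rps5 by 0.39 (SE 0.0796). Their median log2 fold change was −0.27, with −0.24 after quantile normalization and −0.25 without the library of each group richest in markers of other cell types. Genes of DNA replication showed a smaller shift, with a median of −0.18 over 26 tested genes, 22 of them below 0. Of these, 4 were called, the polymerase alpha gene Pola1 (−0.52, SE 0.104), the primase gene Prim1 (−0.37, SE 0.0707), the ligase gene Lig1 (−0.34, SE 0.0636) and Mcm5 (−0.46, SE 0.0684). By camera, adjusted over the 4 groups chosen in this way, both groups were lower (adjusted p = 2.21e-20 and 1.21e-09), with an adjusted p = 0.136 for each with an estimated correlation. Ribosomal protein genes have near-identical copies elsewhere in the genome, so their separate values are uncertain.

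Of 11 oxidative stress genes tested, 9 had estimates above 0 and 3 rose, Hmox1 by 1.88 (SE 0.331), the quinone reductase gene Nqo1 by 1.32 (SE 0.277) and the transcription factor gene Mafg by 0.64 (SE 0.125). The median was 0.42, and by camera the group was higher (adjusted p = 1.07e-05), with an adjusted p = 0.136 with an estimated correlation. Of 11 genes of B cell effector cytokines and receptors, 3 rose, Il10 by 1.99 (SE 0.299), Il12b, which encodes a cytokine subunit, by 1.70 (SE 0.289) and Ccl22 by 1.41 (SE 0.300). The call of Ccl22 was lost in 11 of 23 alternative settings. This group did not pass (adjusted p = 0.178, and 0.455 with an estimated correlation), and its median moved from 0.26 to −0.05 without flox replicate 1. Some members of the 4 groups were taken because they had been called, so the tests of these groups are not independent evidence. Markers of macrophages, which also express Hmox1, were highest in flox replicate 1.

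A first pattern was that Psd fell about as much as Nfkb2. The 2 genes overlap on opposite strands in GRCm38, and their log2 fold changes differed by −0.0961 (SE 0.0783). That SE treats the genes as independent, although both were measured in the same libraries. Psd was at 13.11, 13.51 and 13.43% of Nfkb2 in control and 12.67, 12.45 and 12.34% in flox libraries. The difference of the log2 fold changes lay within 2 SE, as was set for reads shared with Nfkb2. A fixed share of Nfkb2 reads as the sole source of Psd counts would give equal percentages. Values per gene cannot show whether such a share was fixed. Whether reads of Nfkb2 were counted for Psd is therefore not decided. A change of the whole neighbourhood would lower the other genes nearby as well. The 6 tested neighbours (Actr1a, Cuedc2, Fbxl15, Gbf1, Sufu and Tmem180) had a median of −0.0663, from −0.28 to 0.41, and none was called. A fall in Psd transcription itself was not tested and remains open.

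A second pattern was that marginal zone, immature and B-1 genes rose while follicular genes fell. Without the library of each group richest in other cells, 16 of 16 called members kept 0.5 or more of their log2 fold change, and 10 were called. Their direction could not turn, because the groups did not overlap in any called gene, so only the size of the change was tested. The members had been picked as called in the same libraries. Leaving out these 2 libraries lowered the median of the non-B markers from 1.3079 to 0.4375. The median size of the called members' changes fell only from 0.718 to 0.66, so these changes did not rest on the 2 libraries alone. Genes carried by these 2 libraries would hardly have been called, so the test cannot decide on RNA of non-B cells there. The criterion of this test was revised after its value had been seen: as first written it also required a low median of the non-B markers and was undecided, and the remaining 0.4375 (SE 0.1466, 29 markers) leaves such RNA in every flox library open for the genes that rose. The 7 tested follicular genes had a median of −0.2441, and the 4 picked as called falls had one of −0.4804. For these 4, dilution of B cell RNA as the sole cause is less likely. The 16 B cell identity genes had a median of 0.0338 (SE 0.0449), from −0.46 to 0.32. Both SE in this paragraph are the SD over genes divided by the square root of their number. They treat genes as independent, although the identity list had an estimated correlation of 0.393, so they understate the uncertainty. Of the 4 follicular genes, Fcer2a and Cxcr5 were each called in only 1 of the 6 fits without a library. A larger share of marginal zone B cells was undecided, as 10 of 14 of their genes lay above 0 but Cr2, Cd1d1, Notch2 and 2010001M09Rik lay between −0.13 and −0.07, and the genotype acting within the cells was not tested separately and remains open.

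A further pattern was the rise of Hspa1a, Hspa1b, Mt1, Mt2, Hmox1, Atf3, Egr1 and Egr3. The median of these 8 genes was 1.7806 without flox replicate 1 and 2.1974 with all libraries, so their rise was not confined to that library. The genes were picked among called rises, in which the groups did not overlap. A rise in flox replicate 1 alone was thereby left out beforehand, so these values are no test of stress in that library. Different handling of all flox samples was undecided, as 16 other targets of the heat shock factor had a median of 0.1266, and 1 of them, Hsph1, was called (0.48). Handling and genotype cannot be separated here. For the number of genes called by edgeR, 258, the highest other count was 0, and the real grouping was the only 1 of 10 splits to reach it, but 10 splits of 6 libraries are too few for a share under 0.05.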
